A study of Mus musculus with 12 samples.

How the data were processed

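RNA from mouse bone marrow (strain C57BL/6N) was profiled in 12 libraries, 3 in each of 4 groups. The groups are named Sham, Sham-E, MI and MI-E, as in the labels; the labels describe the E groups as given EMPA, and the MI groups as infarcted, with ligation of the LAD in the treatment protocol. Total RNA was isolated with a miRNeasy kit, per the labels' protocols. The submitters' processing notes name CASAVA 1.8, STAR 2.4.0j, RSEM and genome build mm10. How long after surgery marrow was taken, the dose of EMPA, and whether the libraries keep strand are not given in the sources used here. Nothing in the labels says that each library came from a separate mouse. Tests on the spread between libraries therefore refer to these samples, and that spread may be technical.

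The authors deposited a table of expected counts per gene, as RSEM gives them, with no scaling, and a table of TPM values, which RSEM scales by transcript length and to a common total. Both hold the same 53801 genes and 12 columns. Column names gave the group and a number. The numbers were 1, 3 and 4 for Sham, 1, 2 and 3 for Sham-E and for MI, and 2, 3 and 4 for MI-E, whereas sample titles run from 1 to 3 in each group. The Sham-E and MI columns were matched to single samples by group and number, and the Sham and MI-E columns to their group alone. Libraries are named here by group and column number. Gene symbols came from the deposited tables, and positions, exons, transcript lengths and GC content from GENCODE M21 on mm10, which holds 53706 of the IDs.

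Expected counts were rounded to whole numbers. Total counts per library ran from 21175087 to 24606783. Genes were kept by edgeR's filterByExpr with the 4 groups, which left 15119 genes, 15103 of them with annotation. Library sizes were scaled by TMM, with factors from 0.94 to 1.06. The quasi-likelihood F-test of edgeR 4.0.16 (R 4.3.3) was fitted to all 12 libraries with a mean for each group, robust dispersions and 8 residual degrees of freedom. It gave 5 comparisons: MI against Sham, MI-E against MI, Sham-E against Sham, MI-E against Sham-E, and the interaction, which is the MI-E minus MI difference less the Sham-E minus Sham difference. Adjusted p-values are Benjamini-Hochberg values over all genes tested, with a threshold of 0.05, unless said to be adjusted over the list alone. Standard errors are the log2 fold change over the square root of F. Levels of genes are the CPM values of edgeR, counts over the TMM-scaled library size, as mean ± SD over libraries.

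The comparisons, tests, most alternatives, 26 gene lists and the rule for named genes were fixed before the data were examined. The lists cover early B-lineage cells, mature B cells, plasma cells, T and natural killer cells, early granulocyte precursors, immature neutrophils, mature neutrophils, monocytes and dendritic cells, macrophages, eosinophils with basophils and mast cells, erythroid cells, megakaryocytes, stem and progenitor cells, stroma, skeletal muscle, proliferation, the interferon response, inflammation, oxidative phosphorylation, glycolysis, fat oxidation and ketone use, sodium-glucose transport, the glucocorticoid response, immediate early and heat shock genes, ribosomal proteins, and B-cell factors. Lists with at least 5 measured members were tested with camera of limma 3.58.1 on log2 CPM (prior count 2) with the correlation between genes preset at 0.01. The p-values were adjusted over 25 lists and 5 comparisons. With the preset, camera sets the genes of a list against the other genes. Its p-values therefore do not measure how a list as a whole varies between libraries. Camera with an estimated correlation and fry were alternatives. Medians of lists are of edgeR log2 fold changes from the same setting. The level of a list in a library is the mean log2 CPM of its measured members. Levels were compared by exact two-sided permutation tests of 3 against 3 libraries, for which the smallest possible p is 0.1.

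Named genes were, per comparison, up to 8 in each direction with the largest log2 fold change among those past the threshold, with a mean log2 CPM of at least 1 and no overlap between the libraries of the groups. Genes with Gm or Rik symbols, Mir and Snor genes, -ps pseudogenes and antigen receptor V, D or J segments were left out of this part. Where no gene met these terms, the 4 genes in each direction with the smallest p were taken. Up to 4 members with the smallest p came from each list past the list test or with a called member. Ms4a1, Cd79a, Ighm, Ighd, Rag1, Il7r, Cxcr4, Cxcl12, Il7, Slc5a1 and Slc5a2 were always read; other genes of this fixed group are not reported here.

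Fold changes of 2 comparisons were correlated across genes beside 100 simulations of unchanged groups that shared the same libraries. Alternatives were other scaling factors, filters and tools (DESeq2 1.42.0, limma-voom, limma trend on TPM), a fit to the 2 groups compared, abundant genes left out, and each library left out in turn. Those added after the data were seen were a block by column number, offsets for GC content and transcript length, a weight for each library, gene models with over 50% of exon bases in another gene left out, and 3 further contrasts. The mean insert length of each library was recovered from the ratio of expected count to TPM in genes with 1 annotated transcript of 1000 to 5000 bases. Libraries of a group were compared by chi-square over genes, which lay between 14.1 and 208 per degree of freedom, so no library was a copy of another in its group. Libraries of different groups were not compared in this way.

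The edgeR step was tested on simulated counts for the same 15119 genes and libraries. Changed genes were drawn from those with a mean over 2 CPM, and each gene was simulated independently. Recovery at lower counts and shifts shared by many genes of a library are therefore not covered. For MI against Sham it recovered 3 of 67 genes changed 1.5-fold, 31 of 67 changed 2-fold and 63 of 66 changed 4-fold, with 2 false among 99 calls. For MI-E against MI it recovered 5 of 67, 31 of 67 and 64 of 66, with 4 false among 104 calls. The deposited tables were used in full, with no column left out.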

Results

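Gene expression in whole bone marrow was measured by RNA sequencing in mice after a sham operation or myocardial infarction, each without or with EMPA. Each of the 4 groups had 3 libraries, with 21175087 to 24606783 counts per library over 53801 genes, of which 15119 were tested. Correlations of log2 CPM between libraries of a group, taken across genes, were 0.985 to 0.987 in Sham, 0.945 to 0.981 in Sham-E, 0.947 to 0.970 in MI and 0.981 to 0.985 in MI-E. The recovered mean insert length was 285.0 ± 1.53 bp in Sham, 276.0 ± 5.03 bp in Sham-E, 262.9 ± 1.04 bp in MI and 280.4 ± 1.2 bp in MI-E (SD, n = 3 each). Every MI library (262.1 to 264.1 bp) was shorter than every other library (270.2 to 285.9 bp), so insert length is confounded with group in all genes and lists of MI against Sham and of MI-E against MI. Every Sham-E library (270.2 to 279.2 bp) was also shorter than every Sham library (283.2 to 285.9 bp). The same confounding therefore holds for Sham-E against Sham, and for the interaction, which is built from these differences.

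The comparison of MI with Sham asked what infarction changed in the marrow. Some genes of mature neutrophils rose. Wfdc21, a secreted protein of the whey acidic protein family, went from 183 ± 9.63 CPM in Sham to 621 ± 122 CPM in MI (SD, n = 3). The formyl peptide receptors Fpr2 and Fpr1, which guide neutrophils towards bacterial and mitochondrial peptides, went from 147 ± 22.1 to 333 ± 91.1 CPM and from 78.7 ± 5.33 to 141 ± 26.8 CPM. Bglap, which encodes the osteoblast product osteocalcin, fell from 3.51 ± 1.33 to 0.312 ± 0.0751 CPM. It was also low in Sham-E (0.13 to 0.58 CPM), so its low level was not particular to infarction. The histone genes Hist1h2bg and Hist1h1d fell as well. By limma camera with a preset correlation, early B-lineage genes fell as a group (adjusted p = 5.9e-06) and glucocorticoid-responsive genes rose as a group (2.5e-05). Neither call held with an estimated correlation (adjusted p = 0.88).

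With edgeR, 63 genes passed an adjusted p of 0.05, of which 34 rose and 29 fell; 38 had an absolute log2 fold change over 1. At an unadjusted p under 0.05 there were 2945 genes, and in 4123 genes (27.3%, where chance gives 10%) the libraries of MI and Sham did not overlap. Wfdc21 rose by a log2 fold change of 1.76 ± 0.23 (SE; edgeR adjusted p = 0.016), Fpr2 by 1.18 ± 0.20 (0.035) and Fpr1 by 0.84 ± 0.15 (0.038). The subunits of respiratory complex I that mitochondrial DNA encodes, mt-Nd6 and mt-Nd1, rose by 1.61 ± 0.21 (edgeR adjusted p = 0.016) and 1.27 ± 0.20 (0.031). The share of counts in mitochondrial genes was 2.74 ± 0.73% in MI and 1.55 ± 0.10% in Sham (SD, n = 3; exact permutation p = 0.1, the smallest possible). Other rises were AC155729.1 (2.61 ± 0.49), Scrg1, first known for its rise in scrapie-infected brain (2.18 ± 0.38), Tmem268 (1.2 ± 0.23) and Rpl35a, a protein of the large ribosomal subunit (1.13 ± 0.18), with edgeR adjusted p from 0.031 to 0.048.

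Among the falls, the core histone gene Hist1h2bg changed by −2.48 ± 0.47 (log2 ± SE) and the linker histone gene Hist1h1d by −1.84 ± 0.31. Hist1h2bg had 21.4 CPM in Sham 4, against 5.59 and 7.3 in the other Sham libraries, and a change of −1.67 without Sham 4 (edgeR adjusted p = 0.16). Counts over all histone genes were 217 ± 34 CPM in MI and 402 ± 92 CPM in Sham (SD, n = 3; exact permutation p = 0.1). Clstn3, a calsyntenin, changed by −1.63 ± 0.27, the homeobox gene Zfhx2 by −1.53 ± 0.27, the scaffold protein gene Whrn by −1.53 ± 0.28, and Slc9a7, a sodium-proton exchanger of internal membranes, by −1.41 ± 0.25. Bex3 changed by −1.30 ± 0.21 and Spata5l1 by −1.24 ± 0.22. The edgeR adjusted p-values of these 8 genes lay between 0.031 and 0.049. Bglap (−3.47 ± 0.62, edgeR adjusted p = 0.037) was the called member of the stroma list. Its other leading members did not pass. They were Col1a1 and Col1a2, which encode type I collagen (−2.67 ± 0.57 and −2.04 ± 0.60, edgeR adjusted p = 0.062 and 0.11), and the osteoblast factor gene Sp7 (−3.54 ± 1.27, 0.16). The stroma list as a whole did not pass camera (median −0.27, adjusted p = 0.095).

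On mm10, Wfdc21 (ENSMUSG00000051748) lies on chromosome 11 from 83746940 to 83752642. Fpr2 (ENSMUSG00000052270) lies on chromosome 17 from 17887824 to 17893952. Hist1h1d (ENSMUSG00000052565) lies on chromosome 13 from 23553262 to 23560686. Clstn3 (ENSMUSG00000008153) lies on chromosome 6 from 124430759 to 124464794. Cd79a (ENSMUSG00000003379) lies on chromosome 7 from 24897381 to 24902197.

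The early B-lineage list, which holds genes of pro-B and pre-B cells, fell, with a median log2 fold change of −1.37 and all 21 measured members negative (limma camera adjusted p = 5.9e-06). The camera call was lost at adjusted p = 0.88 with an estimated correlation, and no member passed over all genes, while 5 fell when adjusted over the list alone. The mean log2 CPM of the list was 4.64 ± 0.31 in MI and 5.90 ± 0.19 in Sham (SD, n = 3), with no overlap of libraries (exact permutation p = 0.1). Its leading members were Lef1 (−1.55 ± 0.39, edgeR adjusted p = 0.080), Myb (−0.71 ± 0.19, 0.087), Pax5, the factor that commits cells to the B lineage (−1.15 ± 0.31, 0.095), and Tcf3, which encodes E2A (−1.08 ± 0.30, 0.10). Rag1, part of the enzyme that cuts DNA at antigen receptor segments, had 213 ± 75.8 CPM in Sham and 55.9 ± 46.9 CPM in MI (log2 −1.93 ± 1.11, edgeR adjusted p = 0.36).

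The mature B cell list fell too, with a median of −0.35 and 26 of 31 members negative (limma camera adjusted p = 7e-04). That call was lost at adjusted p = 0.88 with an estimated correlation; 0 members passed edgeR over all genes and 1 fell when adjusted over the list alone. Cd79a, the signalling chain of the B-cell receptor, had 265 ± 63.5 CPM in Sham and 105 ± 31.5 CPM in MI (log2 −1.34 ± 0.30, edgeR adjusted p = 0.061). The inhibitory receptor gene Cd22 (−0.60 ± 0.19, 0.12) and Ralgps2 (−0.65 ± 0.19, 0.11) did not pass either. Ms4a1 (−0.55 ± 0.34, edgeR adjusted p = 0.39), Ighm (−0.56 ± 0.29, 0.29), Ighd (−0.15 ± 0.27, 0.79), Il7r (−0.06 ± 0.46, 0.96), Cxcr4 (0.15 ± 0.21, 0.72) and Cxcl12 (−0.22 ± 0.51, 0.84) were read as fixed genes of B-cell identity and homing.

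The mature neutrophil list rose, with a median of 0.44 and 19 of 24 members positive (limma camera adjusted p = 0.00045); 3 members rose over all genes and 9 when adjusted over the list alone. The immature neutrophil list, which holds secondary granule genes, rose with a median of 0.54 and 15 of 16 members positive (adjusted p = 0.00035), with 0 members over all genes and 5 adjusted over the list alone. Both calls were lost at adjusted p = 0.88 with an estimated correlation. The level of the mature list was 8.22 ± 0.43 in MI and 7.8 ± 0.06 in Sham (SD, n = 3; exact permutation p = 0.3), and that of the immature list 10.31 ± 0.45 and 9.69 ± 0.13 (exact permutation p = 0.2). MI 3, at 7.75 and 9.79, lay within the range of Sham in both. Members just short of the threshold were Retnlg (0.98 ± 0.21, edgeR adjusted p = 0.057), Ifitm6 (1.95 ± 0.44, 0.063), Anxa1, the annexin that restrains inflammation (1.14 ± 0.29, 0.075), Lcn2, which binds bacterial siderophores (1.23 ± 0.31, 0.078), and the haptoglobin gene Hp (1.14 ± 0.32, 0.099). The glucocorticoid list rose, with a median of 0.91 and 19 of 20 members positive (limma camera adjusted p = 2.5e-05; adjusted p = 0.88 with an estimated correlation), and 9 members rose when adjusted over the list alone. They were led by Lcn2, the interleukin-1 decoy receptor gene Il1r2 (3.19 ± 0.80, edgeR adjusted p = 0.082), the metallothionein gene Mt1 (1.62 ± 0.41, 0.084) and Klf13 (0.90 ± 0.25, 0.098); Lcn2 and Il1r2 are on the neutrophil lists as well.

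The interferon list fell in MI, with a median of −0.57 and 30 of 34 members negative (limma camera adjusted p = 3.4e-05; adjusted p = 0.88 with an estimated correlation), and 1 member fell when adjusted over the list alone. Its level was 4.68 in MI 2, next to Sham (4.69 to 4.9), against 3.64 in MI 1 and 3.62 in MI 3, and without MI 2 the median was −0.88. Its leading members were Ifit2 (−0.68 ± 0.17, edgeR adjusted p = 0.070), Oasl1 (−1.45 ± 0.42, 0.11), Mx2 (−1.55 ± 0.52, 0.13) and Irf7 (−1.25 ± 0.51, 0.21). The proliferation list fell by a median of −0.28 with 29 of 32 members negative (limma camera adjusted p = 2.1e-05; adjusted p = 0.88 with an estimated correlation), including the replication genes Mcm5 (−0.51 ± 0.14, edgeR adjusted p = 0.084), Pcna (−0.57 ± 0.19, 0.13) and Mcm7 (−0.54 ± 0.18, 0.14) and the spindle checkpoint gene Bub1b (−0.40 ± 0.13, 0.13). The immediate early list, which also moves with sample handling, fell by a median of −0.60 with 18 of 24 members negative (limma camera adjusted p = 0.0057; adjusted p = 0.88 with an estimated correlation). Jun (−1.66 ± 0.41, edgeR adjusted p = 0.079), Junb (−1.10 ± 0.30, 0.094), Zfp36 (−1.2 ± 0.33, 0.095) and Fosb (−3.27 ± 0.88, 0.098) led it, and 6 members fell when adjusted over the list alone. The oxidative phosphorylation list rose by a median of 0.14 with 23 of 33 members positive (limma camera adjusted p = 0.038; adjusted p = 0.90 with an estimated correlation). Among its leading members, Sdhb (0.39 ± 0.11), Cox5b (0.43 ± 0.12) and Uqcrc2 (0.37 ± 0.12) were positive and Ndufa2 (−0.62 ± 0.20) negative, with edgeR adjusted p from 0.099 to 0.13.

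The number of genes called depended on single libraries, from 1 without Sham 1 or Sham 4 to 1224 without Sham-E 1, and 8 of the 63 were models that share over 50% of their exon bases with another gene. DESeq2 called 982. None of the 18 genes named above as past the threshold passed without Sham 1, Sham 3 or Sham 4 (edgeR adjusted p from 0.06 to 0.22). Without Sham-E 2, MI-E 2 or MI-E 4 only 2 of the 18 passed, without MI 3 5, without MI-E 3 8, without MI 1 9 and without MI 2 17, and all 18 passed without Sham-E 1 or Sham-E 3. Without MI 3 the mature B and immediate early lists no longer passed limma camera (medians −0.21 and −0.57, adjusted p = 0.06 and 0.097), without MI 2 the mature neutrophil list did not (0.28, 0.11), and a correction for GC content and length ended the call of the oxidative phosphorylation list (limma camera adjusted p = 0.53, median 0.01), which was also lost without Sham 1, Sham 3, Sham 4, Sham-E 2 or MI 1. The mature B median was −0.23 without Sham 3 and −0.56 without MI 2. Without MI 3 the mature neutrophil median was 0.67 and the glucocorticoid median 0.54.

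**Figure D1:**
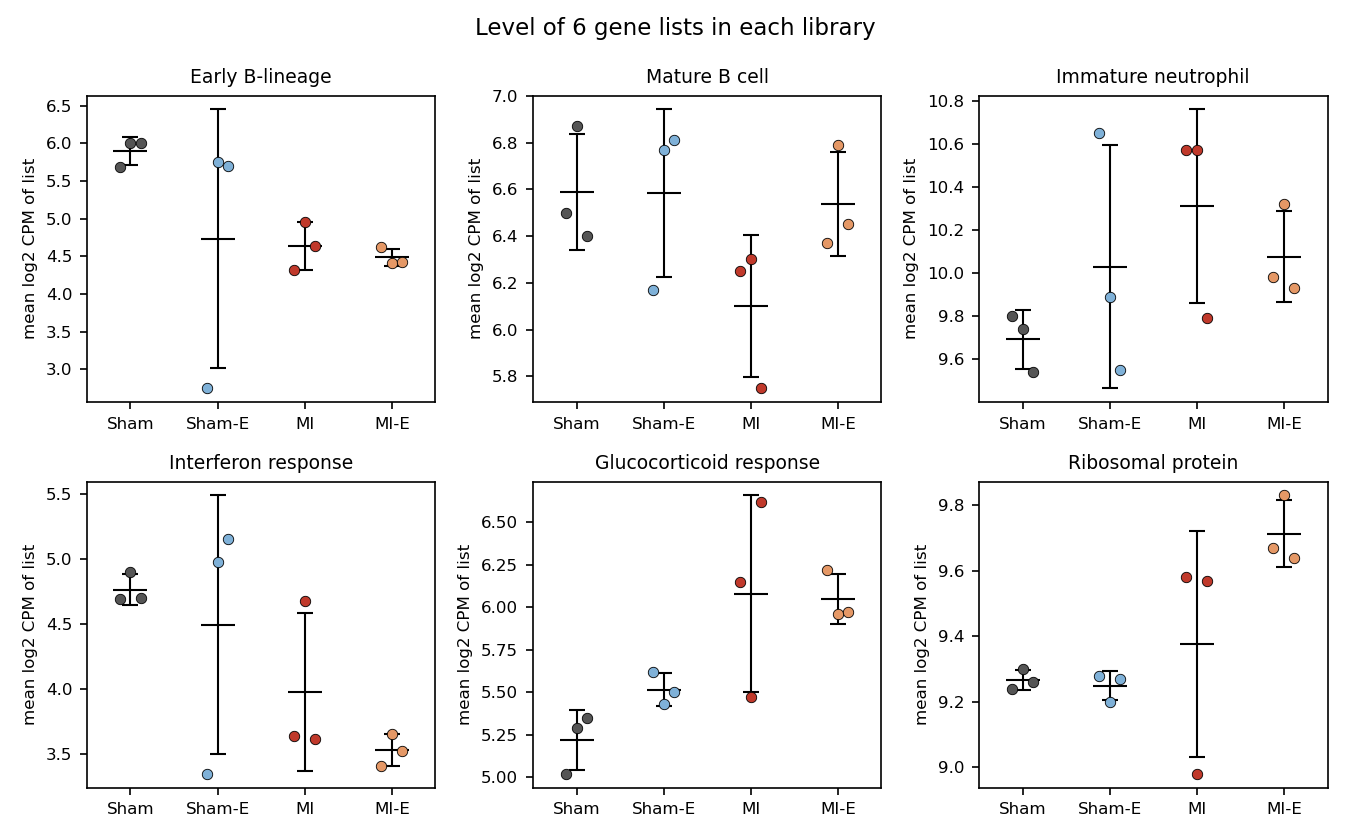
Mean log2 CPM of 6 gene lists (y axis) in each library (points) of the 4 groups (x axis), with group means and SD as bars (n = 3). The early B-lineage level was 5.68 to 6.01 in Sham and 4.32 to 4.95 in MI, and 2.75 in Sham-E 1.

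**Figure D2:**
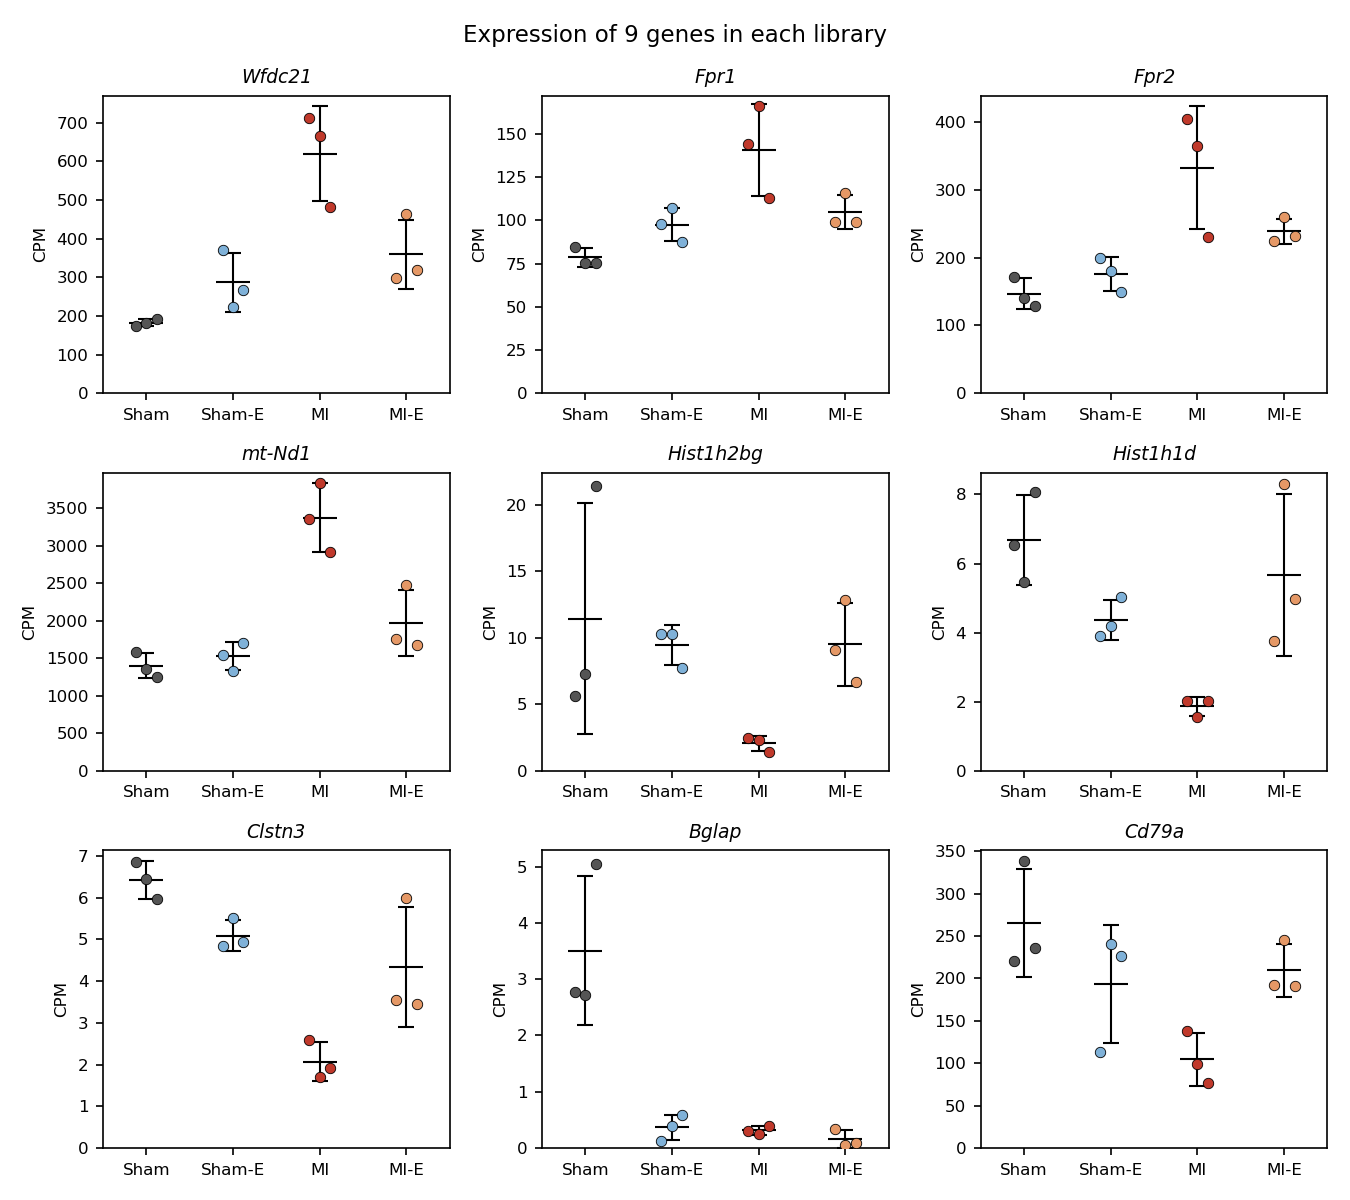
Levels of 9 genes in CPM (y axis) in each library (points) of the 4 groups (x axis), with group means and SD as bars (n = 3). Wfdc21, Fpr1, Fpr2 and mt-Nd1 rose and Hist1h2bg, Hist1h1d, Clstn3 and Bglap fell in MI against Sham; Cd79a did not pass the edgeR threshold.

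The comparison of MI-E with MI asked what EMPA changed in the infarcted marrow. By limma camera with a preset correlation, mature B cell genes rose as a group (adjusted p = 6.7e-05) and mature neutrophil genes fell (0.0043), and neither call held with an estimated correlation (adjusted p = 0.88). The early B-lineage list did not pass, and the difference between the 2 B-cell lists was not tested. The mean log2 CPM of the mature B list was 6.54 ± 0.22 in MI-E, 6.10 ± 0.30 in MI and 6.59 ± 0.25 in Sham (SD, n = 3). Cd79a had 209 ± 30.9 CPM in MI-E and 105 ± 31.5 CPM in MI. Megakaryocyte, proliferation, immediate early and ribosomal protein genes also rose as groups by limma camera with the preset correlation, with adjusted p of at most 0.00029, and each call was lost with an estimated correlation (adjusted p = 0.88).

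With edgeR, 1 gene passed the threshold and 2630 had an unadjusted p under 0.05. In 3275 genes (21.7%, where chance gives 10%) the libraries did not overlap. The gene was B430305J03Rik (ENSMUSG00000053706, chromosome 3 from 61362250 to 61365951), which falls outside the rule for named genes and is given after its values were seen. It had 5.49 ± 0.962 CPM in MI-E and 0.0496 ± 0.0859 CPM in MI (edgeR adjusted p = 0.0027). All of its exon bases lie in exons of Rap2b on the opposite strand, and reads of both genes cannot be told apart if they were counted without regard to strand. Of genes that meet the rule, those with the smallest p did not pass. The mitochondrial gene mt-Nd6 (−1.32 ± 0.21), the transporter gene Slco4c1 (−0.86 ± 0.12), BE692007 (−0.89 ± 0.15) and the myeloid receptor gene Cd33 (−0.88 ± 0.17) were lower in MI-E, at edgeR adjusted p of 0.060 for Slco4c1 and 0.085 for the others. The prefoldin subunit gene Pfdn6 (1.04 ± 0.17), Pdap1 (1.05 ± 0.17), Bex3 (1.23 ± 0.21) and Pebp1 (0.75 ± 0.13) were higher, each at edgeR adjusted p = 0.085. The share of counts in mitochondrial genes was 1.53 ± 0.29% in MI-E and 2.74 ± 0.73% in MI, and counts over all histone genes were 419 ± 96 and 217 ± 34 CPM (SD, n = 3; exact permutation p = 0.1 for each).

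The mature B list rose, with a median of 0.42 and 29 of 31 members positive (limma camera adjusted p = 6.7e-05; adjusted p = 0.88 with an estimated correlation). None of its members passed edgeR over all genes, and 2 rose when adjusted over the list alone. Its leading members were Cd22 (0.77 ± 0.19, edgeR adjusted p = 0.11), Cxcr5, the receptor that brings B cells into follicles (0.78 ± 0.20, 0.12), Cd79a (1.00 ± 0.29, 0.14) and Ciita, the regulator of class II genes (0.47 ± 0.15, 0.16). The level of this list was higher in MI-E than in MI by 0.44 with no overlap of libraries (exact permutation p = 0.1). Ms4a1 (0.25 ± 0.34, edgeR adjusted p = 0.74), Ighm (0.05 ± 0.29, 0.94) and Ighd (0.73 ± 0.27, 0.21) did not pass. The early B-lineage list had a median of −0.14 (limma camera adjusted p = 0.53), with a level of 4.48 ± 0.11 in MI-E and 4.64 ± 0.31 in MI, and Rag1 had a log2 fold change of −0.53 ± 1.08 (edgeR adjusted p = 0.83). Cxcl12, the stromal chemokine that retains B-lineage cells in marrow, had 253 ± 55.3 CPM in MI-E and 108 ± 30.2 CPM in MI (1.23 ± 0.52, edgeR adjusted p = 0.26).

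The mature neutrophil list fell, with a median of −0.38 and 20 of 24 members negative (limma camera adjusted p = 0.0043; adjusted p = 0.88 with an estimated correlation), led by Wfdc21 (−0.79 ± 0.22, edgeR adjusted p = 0.14), the collagenase gene Mmp8 (−0.71 ± 0.23, 0.16), Clec4e (−0.83 ± 0.29, 0.18) and Fpr1 (−0.43 ± 0.15, 0.18). The interferon list fell, with a median of −0.57 and 33 of 34 members negative (limma camera adjusted p = 0.0024; adjusted p = 0.91 with an estimated correlation); Gbp7 (−0.67 ± 0.26), Gbp2 (−0.91 ± 0.39), Stat2 (−0.46 ± 0.20) and Oas2 (−0.98 ± 0.43) led it at edgeR adjusted p from 0.23 to 0.27. The level of the interferon list was 4.68 in MI 2, against 3.64 and 3.62 in the other MI libraries, and without MI 2 its median was −0.16 (limma camera adjusted p = 0.56). For both lists 0 members passed edgeR, over all genes or adjusted over the list alone.

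The megakaryocyte list rose by a median of 0.74 with 21 of 24 members positive (limma camera adjusted p = 0.00029), led by the platelet glycoprotein genes Gp9 (1.48 ± 0.44, edgeR adjusted p = 0.15) and Gp5 (1.19 ± 0.40, 0.17), Treml1 (1.57 ± 0.56, 0.19) and Vwf (1.00 ± 0.38, 0.21). The proliferation list rose by 0.29 with 28 of 32 members positive (limma camera adjusted p = 6e-06), led by E2f1 (0.83 ± 0.20), Mcm5 (0.57 ± 0.14) and the ribonucleotide reductase gene Rrm2 (0.83 ± 0.20), each at edgeR adjusted p = 0.11; 10 members rose when adjusted over the list alone. The list of T and natural killer cells rose by 0.29 with 23 of 28 members positive (limma camera adjusted p = 0.0043), led by the T-cell kinase gene Lck (0.77 ± 0.24, edgeR adjusted p = 0.16). Each of these calls was lost at adjusted p = 0.88 with an estimated correlation.

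The immediate early list rose by 0.83 with 16 of 24 members positive (limma camera adjusted p = 0.00029) and 10 members adjusted over the list alone, led by Junb (1.67 ± 0.31, edgeR adjusted p = 0.085), Zfp36 (1.46 ± 0.33, 0.11), Fosb (3.82 ± 0.90, 0.11) and Fos (1.77 ± 0.43, 0.12). The inflammation list rose by 0.38 with 20 of 27 members positive (limma camera adjusted p = 0.014), where Junb was followed by the chemokine genes Ccl3 (1.66 ± 0.45, edgeR adjusted p = 0.13) and Ccl4 (2.25 ± 0.73, 0.17) and Ier3 (0.92 ± 0.30, 0.17), with 2 members adjusted over the list alone. The ribosomal protein list rose by 0.32 with 32 of 34 members positive (limma camera adjusted p = 3.8e-07) and 8 members adjusted over the list alone, among them Rplp1 (0.86 ± 0.20, edgeR adjusted p = 0.11) and Rpl11 (0.67 ± 0.17, 0.12). The oxidative phosphorylation list rose by 0.22 with 27 of 33 members positive (limma camera adjusted p = 0.00032) and 5 adjusted over the list alone, led by Ndufa2 (1.03 ± 0.20, edgeR adjusted p = 0.085) and Uqcrq (0.75 ± 0.18, 0.11). All 4 calls were lost at adjusted p = 0.88 with an estimated correlation. The level of the ribosomal protein list was 8.98 in MI 2, against 9.58 and 9.57 in the other MI libraries and 9.64 to 9.83 in MI-E, and without MI 2 its median was 0.13 (limma camera adjusted p = 0.0041). The level of the immediate early list was 6.59 in MI-E 3, against 5.66 and 5.67 in the other MI-E libraries, and without MI-E 3 its median was 0.31 (0.015). Across 9578 genes, the log2 fold changes of MI-E against MI followed GC content (rho 0.51) and transcript length (rho −0.33), and genes are not independent replicates. Corrected for both, the medians were 0.18 for ribosomal proteins (limma camera adjusted p = 0.002), 0.11 for oxidative phosphorylation (0.035), 0.16 for inflammation (0.049) and 0.67 for immediate early genes (0.00023). The immature neutrophil (−0.33, 0.014), macrophage (−0.27, 0.044) and stroma (0.34, 0.042) lists, which did not pass uncorrected (adjusted p = 0.098, 0.14 and 0.19), passed limma camera after this correction.

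DESeq2 called 490 genes. B430305J03Rik did not pass with limma-voom (adjusted p = 0.061) or, in edgeR, with library weights (adjusted p = 0.15; range over all settings 1.1e-10 to 0.15). Of the libraries left out in turn, MI 1 moved the number of genes to 988, Sham-E 1 to 42 and Sham-E 2 to 2, and without overlapping gene models no gene passed edgeR (2533 at an unadjusted p under 0.05). The mature neutrophil list was lost without MI 1 or MI 2, the interferon list without MI 2, the T and natural killer cell list without MI 3 or MI-E 3, and the inflammation list without MI 1, MI 3 or MI-E 3. Medians without a library were −0.36 (MI 1) and −0.12 (MI 2) for mature neutrophils, 0.24 (MI 3), 0.22 (MI-E 3) and 0.48 (MI 1) for T and natural killer cells, and 0.29 (MI 1), 0.32 (MI 3) and 0.16 (MI-E 3) for inflammation. They were 0.24 (MI 3) and 0.27 (MI-E 3) for mature B cells, 0.14 (MI-E 3) for oxidative phosphorylation and 0.18 (MI-E 4) for proliferation, which still passed.

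Whether EMPA moved genes against the direction of infarction was asked across all genes. Log2 fold changes of MI against Sham and of MI-E against MI had r = −0.595 across 15119 genes, where unchanged groups that share the MI libraries gave −0.735 (from −0.755 to −0.711 in 100 simulations). The covariance was −0.192, against −0.12 simulated, a difference of −0.071. Of the 63 genes called in MI against Sham, 61 had the opposite sign in MI-E against MI, and the simulated mean was 61.2. Only B430305J03Rik was called in both comparisons, which share the MI libraries. In MI-E against Sham-E, 43 of the 63 kept the sign they had in MI against Sham. In Sham-E against Sham, which shares the Sham libraries with that comparison, 60 of the 63 did, and no simulated count was made for it. The r was less negative than in any of the 100 simulations, while the covariance was more negative than their mean. With Sham-E against Sham, fold changes of MI against Sham had r = 0.589 (0.247 simulated) and a covariance of 0.139 (0.038 simulated); the difference of 0.101 was 0.017 without Sham-E 1. Genes are not independent replicates, so these values carry no p.

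The comparison of Sham-E with Sham asked what EMPA changed without infarction. By limma camera with a preset correlation, early B-lineage, erythroid and megakaryocyte genes fell as groups (adjusted p of at most 3.8e-05) and neutrophil genes rose as groups (at most 0.0081), and none of these calls held with an estimated correlation (adjusted p = 0.88). The erythroid and immature neutrophil lists did not pass without Sham-E 1. No gene passed edgeR, with 287 genes at an unadjusted p under 0.05, 1358 genes without overlap of libraries (8.98%, where chance gives 10%) and 2 genes past the threshold with DESeq2. Genes with the smallest p were the receptor genes Gpr141 (0.48 ± 0.12) and Fcgr4 (0.74 ± 0.20), Zfp992 (0.68 ± 0.19), Kbtbd11 (0.44 ± 0.13), the kinase gene Src (−1.13 ± 0.30), Col1a1 (−1.82 ± 0.55), the eosinophil peroxidase gene Epx (−0.67 ± 0.22) and Mrvi1 (−1.18 ± 0.39), each at edgeR adjusted p = 1. The early B-lineage list fell, with a median of −0.64 and all 21 members negative (limma camera adjusted p = 2.6e-10; adjusted p = 0.88 with an estimated correlation). Its level was 2.75 in Sham-E 1, 5.75 in Sham-E 2 and 5.70 in Sham-E 3, against 5.68 to 6.01 in Sham, and without Sham-E 1 its median was −0.19 (−1 without Sham-E 2).

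Other lists also depended on Sham-E 1. Erythroid genes fell by a median of −0.34 (limma camera adjusted p = 6.1e-07), the eosinophil, basophil and mast cell list by −0.13 (0.0035), and the lists of early granulocyte precursors and immature neutrophils rose by 0.42 (0.004) and 0.32 (0.00057); without Sham-E 1 none of the 4 passed, and the medians of the erythroid and early granulocyte lists turned to 0.13 and −0.04. Leading members were Prg3 (−0.71 ± 0.24) and Prg2 (−0.60 ± 0.23) of eosinophil granules, the proteases Ctsg (0.93 ± 0.47) and Prtn3 (0.73 ± 0.39) of primary granules, and Chil3 (1.04 ± 0.39), all at edgeR adjusted p = 1. The megakaryocyte list fell by −0.56 (limma camera adjusted p = 3.8e-05) in all 12 settings that left out 1 library, with a median from −0.9 to −0.37. Its level did not part the groups (exact permutation p = 0.3). It was 2.89 in Sham 3, inside the Sham-E range of 2.84 to 3.57, and 4.1 and 4.08 in Sham 1 and Sham 4. The mature neutrophil and glucocorticoid lists rose by 0.17 (0.0081) and 0.26 (0.0069), and the stroma and skeletal muscle lists fell by −0.08 (0.00019) and −0.56 (0.012). The mature neutrophil list was lost without Sham 4 or Sham-E 2, the glucocorticoid list without Sham 1 and the stroma list without Sham-E 2 (median 0.13). The stroma median, near 0, ranged from −0.78 without Sham-E 3 to 0.13 and was 0.11 without Sham 1. Without Sham-E 3 the medians were −1.07 for erythroid cells, 0.67 for early granulocyte precursors, 0.54 for immature neutrophils, 0.3 for mature neutrophils and −0.35 for the eosinophil list. The glucocorticoid median was 0.13 without Sham 1 and 0.14 without Sham-E 1, and the mature neutrophil median 0.11 without Sham-E 1. The eosinophil median was −0.21 without Sham 1, −0.22 without Sham 4 and −0.26 without Sham-E 2. The megakaryocyte median was −0.9 without Sham 3 and −0.37 without Sham 4. The skeletal muscle list, with 11 measured members, was lost without Sham 3, Sham 4, Sham-E 1, Sham-E 3, MI 1, MI 2, MI 3, MI-E 2 or MI-E 3. Within the stroma list, Bglap had 0.365 ± 0.225 CPM in Sham-E and 3.51 ± 1.33 CPM in Sham (−3.25 ± 0.60, edgeR adjusted p = 1). In each of these 9 lists the camera adjusted p was 0.88 with an estimated correlation. No member passed edgeR over all genes, and 1, of the stroma list, fell when adjusted over the list alone.

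The comparison of MI-E with Sham-E asked what infarction changed under EMPA. By limma camera with a preset correlation, interferon-response genes fell as a group, and ribosomal protein, respiratory chain, megakaryocyte and erythroid genes rose as groups (adjusted p of at most 7.3e-05). None of these calls held with an estimated correlation (adjusted p = 0.88), and the erythroid list was lost without Sham-E 1. All 34 interferon genes were negative, with a median of −0.99 (limma camera adjusted p = 1.2e-11), and 17 fell when adjusted over the list alone. The level in Sham-E 1, at 3.35, lay below those of the MI-E libraries (3.41 to 3.66), and the levels did not part the groups (exact permutation p = 0.4). Ifit2 had 14.3 ± 0.87 CPM in MI-E and 24.5 ± 1.38 CPM in Sham-E (−0.77 ± 0.17, edgeR adjusted p = 0.24), and Cxcl10 (−1.87 ± 0.45) and Ifi44 (−3.32 ± 0.86) had the same adjusted p. All 34 ribosomal protein genes were positive, with a median of 0.44 (limma camera adjusted p = 8.8e-16), and 25 rose when adjusted over the list alone, among them Rps23 (0.72 ± 0.18) and Rpl8 (0.65 ± 0.17). The oxidative phosphorylation list rose by 0.26 (limma camera adjusted p = 3e-10; 12 adjusted over the list alone), led by Cox5b (0.59 ± 0.12) and Ndufv1 (0.52 ± 0.13). The megakaryocyte list rose by 0.98 (1e-06; 8 adjusted over the list alone), with Itga2b, the platelet fibrinogen receptor chain, at 85.7 ± 12.1 CPM in MI-E and 42.3 ± 4.25 CPM in Sham-E (1.02 ± 0.23, edgeR adjusted p = 0.24).

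The erythroid list rose by 0.59 (limma camera adjusted p = 7.3e-05; without Sham-E 1 its median was 0.08, adjusted p = 0.9, and it was 1.24 without Sham-E 3 and 0.28 without MI-E 4), with Car1 at 0.88 ± 0.52 (edgeR adjusted p = 0.48), and the glucocorticoid list by 0.46 (0.011), with the metallothionein gene Mt2 at 1.04 ± 0.31 (0.25). The eosinophil, basophil and mast cell list rose by 0.24 (limma camera adjusted p = 0.025; 5 adjusted over the list alone), with Prg2 at 1.32 ± 0.23 (edgeR adjusted p = 0.24), and the skeletal muscle list by 0.67 (0.014), with Ckm at 1.37 ± 0.258 CPM in MI-E and 0.301 ± 0.222 CPM in Sham-E. The early B-lineage list had a median of −0.77 (limma camera adjusted p = 0.057). All 8 list calls were lost at adjusted p = 0.88 with an estimated correlation. No gene passed edgeR (smallest adjusted p = 0.12, for Perp at 1.34 ± 0.19), with 2031 genes at an unadjusted p under 0.05 and 135 called by DESeq2; the count was 117 without Sham-E 1 and 59 without MI 2. With library weights, which gave Sham-E 1 a weight of 0.223, it was 3285.

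In MI-E against Sham-E, fold changes followed transcript length (rho −0.50) and GC content (rho 0.37) across genes. Corrected for both, the ribosomal protein list had a median of 0.26 (limma camera adjusted p = 6.6e-08) and the oxidative phosphorylation list 0.12 (0.00054), while the eosinophil list no longer passed (median 0.16, 0.076). The lists of early granulocyte precursors (−0.48, 0.008) and stroma (0.26, 0.0038) passed limma camera after this correction and not before it (adjusted p = 0.14 and 0.095). The eosinophil list was also lost without Sham-E 1, MI 2 or MI-E 3, and the skeletal muscle list without MI 2 (median 0.5). The skeletal muscle median was 0.29 without MI-E 2 and 0.34 without MI-E 4, and the glucocorticoid median 0.71 without Sham-E 1. Counts over all histone genes were 419 ± 96 CPM in MI-E and 316 ± 45 CPM in Sham-E (SD, n = 3; exact permutation p = 0.1).

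The interaction asked whether the effect of EMPA differed between infarcted and sham mice. By limma camera with a preset correlation, megakaryocyte, erythroid, proliferation and B-lineage genes differed as groups towards higher and neutrophil genes towards lower levels with EMPA after infarction (adjusted p of at most 0.018). None of these calls held with an estimated correlation (smallest adjusted p = 0.88), and the early B-lineage list was lost without Sham-E 1 (median −0.07) or MI 1. With edgeR, 1 gene passed, again B430305J03Rik (7.39 ± 0.79, adjusted p = 0.0072), whose fitted change depends on the prior count since its MI libraries are near 0, with 2042 genes at an unadjusted p under 0.05 and 140 called by DESeq2. It did not pass with limma-voom (adjusted p = 0.1) or, in edgeR, with a block by column number (0.14) or library weights (0.07), and its edgeR adjusted p was at most 0.038 with any 1 library left out. Genes that meet the rule did not pass. They were led by Pfdn6 (1.38 ± 0.24), Bex3 (1.55 ± 0.29), Hist1h1d (2.22 ± 0.43), Slco4c1 (−1.06 ± 0.17), Gpr141 (−0.96 ± 0.17), the proton-sensing receptor gene Gpr65 (−1.16 ± 0.21) and Clec4a1 (−1.31 ± 0.24), each at edgeR adjusted p = 0.22. Wfdc21 (−1.44 ± 0.32, edgeR adjusted p = 0.24), Cd79a (1.46 ± 0.41, 0.26) and Junb (2.11 ± 0.43, 0.24) did not pass. By limma camera 11 lists passed. The difference was positive for megakaryocyte genes (median 1.28, limma camera adjusted p = 6e-06), led by Treml1 (2.80 ± 0.80), Gp9 (2.17 ± 0.62) and Gp5 (1.97 ± 0.56), and for mature B cell genes (0.35, 0.014). It was negative for immature and mature neutrophil genes (−0.70 and −0.59, limma camera adjusted p = 0.0035 and 0.00075), led by Wfdc21, Mmp8 (−1.13 ± 0.32) and Chil3 (−1.44 ± 0.55). The mature B list was lost without Sham 3, Sham-E 1, MI 3 or MI-E 3, and the immature neutrophil list without MI 1. Medians were −0.28 for immature neutrophils without Sham-E 1 and −0.29 for mature neutrophils without MI 2. The glucocorticoid list passed limma camera after the correction for GC content and length (median −0.48, adjusted p = 0.048) and not before it (0.1). The count of genes was 150 without MI 1 and 2 without Sham-E 2.

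Sodium-glucose transporter genes were read as a fixed group. Slc5a1, which encodes SGLT1, had 0 to 1 counts in the 12 libraries and was not tested. Slc5a2, which encodes SGLT2, had 0 to 33 counts, with 1.14 ± 0.484 CPM in MI-E and 0.181 ± 0.159 CPM in MI (2.66 ± 0.94, edgeR adjusted p = 0.19). Without infarction the direction with EMPA was the other way, with 0 to 9 counts in Sham-E and 10 to 21 in Sham. Only 3 of the 8 members of this list were measured, so it was not tested. Il7, a growth factor for B-cell precursors, had 2 to 17 counts.

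Lists that passed in none of the 5 comparisons are given by their smallest limma camera adjusted p. It was 0.10 for plasma cells (median −0.22, MI against Sham), 0.14 for macrophages (−0.26, MI-E against MI), 0.17 for glycolysis (0.34, MI against Sham), 0.17 for fat oxidation and ketone use (0.10, Sham-E against Sham), 0.30 for monocytes and dendritic cells (−0.12, MI-E against Sham-E), 0.37 for stem and progenitor cells (−0.06, Sham-E against Sham) and 0.60 for B-cell factors (0.16, MI-E against MI). Some of these passed limma camera in an alternative. With a block by column number these were plasma cells (adjusted p = 0.047) and macrophages (0.017) in MI against Sham, fat oxidation in Sham-E against Sham (0.038), glycolysis in MI-E against Sham-E (0.037) and macrophages in the interaction (0.017). With 1 library left out they were glycolysis in MI against Sham (limma camera adjusted p = 0.013, without MI 3), Sham-E against Sham (0.011, without Sham-E 3) and MI-E against Sham-E (0.00089, without Sham-E 1). They were also macrophages in MI-E against MI (limma camera adjusted p = 0.045, without MI-E 4) and, without Sham-E 2, in Sham-E against Sham (0.015) and the interaction (0.011). In Sham-E against Sham, stem and progenitor cells passed without Sham 3 (limma camera adjusted p = 0.04) and B-cell factors without Sham-E 1 (0.039). In MI against Sham the megakaryocyte, erythroid and ribosomal protein lists did not pass (medians −0.27, −0.26 and 0.11, limma camera adjusted p = 0.25, 0.30 and 0.081). In every list that passed, the median, the mean and the test had the same sign.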

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

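All tests of explanations in this part were chosen after the result they concern was seen, as were the correction for GC content and length and the comparison of overlapping gene models; the interaction test was chosen earlier, and the redrawing of EMPA labels within each operation was added later, with its bound set before it was run.

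By the interaction test, 1 gene and 11 lists passed as differing between the effect of EMPA after infarction and after a sham operation. The gene was B430305J03Rik (log2 7.39, edgeR adjusted p = 0.0072), whose fold depends on the prior count since its MI libraries are near 0. It fell short of the threshold in 3 of 12 alternatives, limma-voom (adjusted p = 0.1), a block by column number (0.14) and library weights (0.07), with adjusted p from 1.8e-11 to 0.14 and log2 values from 1.92 to 10.68 over all settings. It was not tested where overlapping gene models were left out. Lists with a positive difference by limma camera were megakaryocytes (median 1.28, adjusted p = 6e-06; 5 members adjusted over the list alone), immediate early genes (0.86, 0.0014; 7 members), erythroid cells (0.72, 0.00025), stroma (0.39, 0.0042), early B-lineage cells (0.35, 0.018), mature B cells (0.35, 0.014), proliferation (0.34, 2e-05), ribosomal proteins (0.30, 2.5e-05) and oxidative phosphorylation (0.17, 0.0078; 1 member). Lists with a negative difference were immature neutrophils (−0.70, 0.0035) and mature neutrophils (−0.59, 0.00075; 3 members). None passed limma camera with an estimated correlation (smallest adjusted p = 0.88) or fry (smallest 0.40). The early B-lineage list was lost without Sham-E 1 (median −0.07) or MI 1 (0.22), the mature B list without Sham 3, Sham-E 1 or MI 3 (0.2 each) or MI-E 3 (0.25), the immature neutrophil list without MI 1 (−0.65), the stroma list without Sham-E 2 (0.2), and the oxidative phosphorylation list without MI-E 3 (0.11) and after the correction for GC content and length (median 0.09, adjusted p = 0.13). Lists that still passed moved as well. The early B-lineage median was 0.7 without Sham-E 2 or Sham-E 3 and 0.57 without MI 2. The erythroid median was 0.27 without Sham-E 1, 0.44 without MI-E 4, 1.26 without MI 3 and 1.45 without Sham-E 3. The stroma median was 0.2 without Sham 1, 0.24 without MI 2, 0.65 without MI-E 3, 0.69 without Sham 3, 0.9 without MI 3 and 1.07 without Sham-E 3. Without MI 2 it was 0.11 for ribosomal proteins, 0.09 for oxidative phosphorylation and −0.29 for mature neutrophils. It was −0.28 for immature neutrophils without Sham-E 1 and 0.41 for immediate early genes without MI-E 3.

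With EMPA labels redrawn within each operation, 15 of 100 splits, the real one included, gave at least 1 gene, and the highest other gave 4, so chance could not be excluded for the gene count of 1. For lists, adjusted within this comparison alone, 12 passed in the real split, 28 of the 100 splits gave as many and the highest other gave 18, so chance could not be excluded for the lists either. In 100 draws over all 12 libraries, 3 gave at least 1 gene (highest other 468) and 25 at least 12 lists (highest other 17). Those draws mix sham and infarct libraries, so a difference between the operations enters both their spread and their contrast, and they decide nothing about chance. The draw with 468 genes, against 1 in the real grouping, set all Sham libraries, Sham-E 2, Sham-E 3 and MI 3 against the rest. That is sham against infarct with Sham-E 1 and MI 3 exchanged. Infarct against sham with every library in place, averaged over both treatments, gave 43 genes. The source of the larger count was not tested.

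Early B-lineage genes were lower in MI than in Sham, with a difference in mean log2 CPM of −1.26 (exact permutation p = 0.1, the smallest possible), with library SD of up to 0.31. Bias by GC content or gene length was argued against, since the median of the list after correction was −1.33. Dilution by a larger share of neutrophil RNA would lower every other cell type alike. The lowest of 10 other cell type lists outside the neutrophil series differed by −0.50, and their median was −0.24, so dilution alone was argued against as well. A loss of early B-lineage cells may explain that 21 of 21 members were lower. It stays open, because whole marrow RNA cannot separate fewer cells from less RNA per cell.

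Between MI and Sham, 9 gene models were all or none, with at most 3 counts in every library of 1 group and at least 20 in every library of the other; 4 were found in Sham and 5 in MI. All 9 share over 50% of their exon bases with another gene, against 2.96% of 13173 other genes (Fisher's exact test, p = 2e-14). Those are the genes whose higher mean count of the 2 groups lay between the lowest and highest of the 9. That range is wide, so they were not matched to the 9 by count. For AY036118 and Hist2h2bb, reads counted for the overlapping gene were argued against as the only cause. The highest total of AY036118 and Gm42418 in MI was 617 CPM, against at least 1040 in Sham, and Gm42418 had a mean of 363 CPM in MI where AY036118 had 737 in Sham. Gm42418 itself ranged from 3315 to 14683 counts within MI. A total that varies this much cannot show whether some reads of AY036118 were moved as well. Low counts of AY036118 were not confined to infarcted marrow. This model had 0 counts in Sham-E 3 and 2232 in Sham-E 2, against 12353 to 20945 in Sham and 6796 to 13620 in MI-E. The highest total of Hist2h2bb and Gm20628 in MI was 0.588 CPM, against at least 1.83 in Sham. The other 7 (100% of them overlapping; Fisher's exact test, p = 2.1e-11), B430305J03Rik with its partner Rap2b among them, may reflect reads assigned differently between overlapping gene models. For Gm20402, 1 of the 7, the total with Foxo1 was lower in MI (at most 55.8 CPM) than in Sham (at least 62.3), but Foxo1 at a mean of 47.9 CPM in MI is high enough to hold the 3.18 CPM of the model in Sham, so reassignment stays open there. Shorter inserts in the MI libraries (a mean difference of −22.0 bp) stay open as a source, because every MI library (262.1 to 264.1 bp) was shorter than every Sham library (283.2 to 285.9 bp). A change in transcription stays open too: 8 of the 9 lie opposite to their partner, and whether reads were counted by strand is not given. If they were, opposite partners could not exchange reads. Of the 63 genes called in MI against Sham, 8 overlap in this way (12.7%, against 3.23% of the genes tested; Fisher's exact test, p = 0.00091).

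The library Sham-E 1 had an early B-lineage level of 2.75. By this level, an exchange of labels with an infarct library of this set was argued against. The highest among MI and MI-E libraries was 4.95, below the lowest of the remaining sham libraries (5.68), so none of them has a sham level. Other values leave an exchange open. The interferon level was 4.68 in MI 2, next to Sham (4.69 to 4.9), and 3.35 in Sham-E 1. Across genes, Sham-E 1 had r from 0.941 (MI 3) to 0.968 (MI 1) with infarct libraries, against 0.959 (Sham-E 2) and 0.945 (Sham-E 3). Samples outside the 12 libraries could not be tested. A lower depth was argued against by the total of Sham-E 1, 23.6 M counts, within the range of the others. Fewer early B cells with the other cell types in unchanged proportion was argued against too, since the other lists moved apart over a range of 3.63 on the log2 scale, from 1.16 for early granulocyte precursors to −2.47 for erythroid cells, and the largest difference between the other Sham-E libraries was 1.44. A response to EMPA in this mouse alone could explain it and stays open, with the lowest level of the other Sham-E libraries at 5.70; a sample taken or handled differently was not tested.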

How the results depend on the processing

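Alternatives chosen after the data were seen were the block by column number, the GC content and length offsets, the library weights and the removal of overlapping gene models.

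Of the alternative values of the main results, 315 kept their side of the threshold or stayed close (counts within 1.5 times), 37 moved further, 14 no longer passed and 6 newly passed. The 63 genes named for MI against Sham are not the 63 called. Beyond the 18 given above as past the threshold, most did not pass and could not fall short of it. Of the 1622 alternative values of the named genes, 1331 kept their direction and side of the threshold and 178 fell short of it. A further 102 newly passed it, 11 had the other sign short of it and 0 reversed past it. Below, each number is a count of genes past an adjusted p of 0.05, where edgeR gave 63 for MI against Sham, 1 for MI-E against MI, 0 for Sham-E against Sham, 0 for MI-E against Sham-E and 1 for the interaction. Except where the construction shows it, the cause was not tested.

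With no filter beyond a count above 0 there were 156 in MI against Sham and 33 in MI-E against MI. The DESeq2 Wald test called 982, 490, 2, 135 and 140 in the order above, and 62 of the 63 genes were among its 982. Limma trend gave 276, 85 and 18 in MI against Sham, MI-E against MI and the interaction on log2(TPM + 1), and 259, 73 and 12 on log2(TPM + 0.1). A fit to only the libraries of the 2 groups compared gave 344 in MI against Sham and 3 in MI-E against MI. Limma-voom gave 0 in the interaction, with 2070 genes at an unadjusted p under 0.05. GC and length offsets gave 105 in MI against Sham. Library weights, from 0.223 for Sham-E 1 to 4.56 for Sham-E 2, gave 340, 2, 2 and 3285 in the first 4 comparisons. Without overlapping gene models MI-E against MI and the interaction had 0, since B430305J03Rik is such a model, with 2533 and 1963 genes at an unadjusted p under 0.05.

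A block by title number could not be run, because the column numbers of Sham and MI-E differ from their titles, so those 6 columns cannot be matched to single titles. A replicate block by column number left 1 gene in MI against Sham and 0 in the interaction (1042 at an unadjusted p under 0.05). The numbers did not pair the libraries: of 13 pairs that share a number, 4 had a residual correlation across genes over 0.1, the range was −0.21 to 0.15, and 4 of 12 libraries correlated best with their own number.

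Leaving out 1 library at a time gave 1 to 1224 genes in MI against Sham: 1, 3 and 1 without Sham 1, 3 and 4; 1224, 12 and 122 without Sham-E 1, 2 and 3; 115, 285 and 7 without MI 1, 2 and 3; 6, 33 and 9 without MI-E 2, 3 and 4. MI-E against MI ranged from 1 to 988, with 42 without Sham-E 1, 2 without Sham-E 2 and 988 without MI 1. MI-E against Sham-E ranged from 0 to 117, with 117 without Sham-E 1 and 59 without MI 2. The interaction ranged from 1 to 150, with 2 without Sham-E 2 and 150 without MI 1.

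By limma camera with an estimated correlation, 0, 0, 0, 0 and 0 lists passed in the 5 comparisons (smallest adjusted p = 0.88; 1, 0, 1, 2 and 0 lists at an unadjusted p under 0.05), and by the directional test of fry also 0 in each (1, 2, 0, 4 and 2 lists). The mixed test of fry, which asks for change in either direction, called 2, 1, 0, 2 and 0 lists: mature neutrophils and oxidative phosphorylation in MI against Sham (adjusted p = 0.012 for each), oxidative phosphorylation in MI-E against MI (0.019), and oxidative phosphorylation and the eosinophil list in MI-E against Sham-E (0.012 and 0.023). With the preset correlation, 9, 10, 10, 8 and 11 passed. The covariance of MI against Sham with MI-E against MI, less its simulated mean, was −0.071, and ranged from −0.096 to −0.043 with 1 library left out (without MI 2 and MI 1). With Sham-E against Sham it was 0.101, 0.066 in genes with a mean log2 CPM of at least 3, and 0.017 to 0.146 with 1 library left out (without Sham-E 1 and Sham-E 3).

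At this depth and number of libraries, 1.5-fold changes were found in 3 of 67 simulated genes for MI against Sham, so smaller changes were mostly out of reach.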

Other observations

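The contrasts averaged over groups were chosen after the data were seen.

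Averaged over both treatments, infarct against sham gave 43 genes with edgeR (21 higher, 22 lower), among them Wfdc21 (1.05), Wfdc17 (2.12), Perp (1.02), Relt (0.53), Ndufa8 (0.55), Ifit2 (−0.73), Mpzl3 (−1.33) and the potassium channel gene Kcna3 (−1.49), each as a log2 fold change. The early B-lineage list had a median of −1.05, interferon −0.76, glucocorticoid 0.66 and ribosomal proteins 0.29; no list passed limma camera with an estimated correlation (smallest adjusted p = 0.72). Averaged over both operations, EMPA gave 0 genes with edgeR (869 at an unadjusted p under 0.05), with a median of 0.27 for mature B genes (limma camera adjusted p = 1.5e-05), −0.27 for early B-lineage genes (1.1e-05) and 0.15 for ribosomal proteins (1.9e-06), and the smallest adjusted p with an estimated correlation was 0.76. The early B-lineage level was 2.75 in Sham-E 1 and 5.75 and 5.70 in the other Sham-E libraries. The median of this list was −0.64 in Sham-E against Sham and −0.19 without Sham-E 1, and it did not pass limma camera in MI-E against MI (−0.14, adjusted p = 0.53). MI-E against Sham gave 0 genes with edgeR (2070 at an unadjusted p under 0.05). By limma camera with the preset correlation, the early B-lineage (median −1.25, adjusted p = 4.3e-10) and interferon (−1.19, 4.4e-16) lists were lower. The glucocorticoid (0.87, 2e-05) and ribosomal protein (0.46, 4.4e-16) lists were higher, and the mature B list did not pass (−0.01, 0.8). With an estimated correlation no list passed (smallest adjusted p = 0.52).

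The difference in mean insert length was −22.0 bp for MI minus Sham and 17.5 bp for MI-E minus MI (exact permutation p = 0.1 for each, the smallest possible). It was −9.0 bp for Sham-E minus Sham (exact permutation p = 0.1) and 4.4 bp for MI-E minus Sham-E (0.2).

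Each comparison of 3 against 3 libraries has 10 splits, too few for a share under 0.05 in a test of chance. In MI against Sham 63 genes were called in the real split and at most 0 in the others (1 of 10 splits as large), and 9 lists against at most 13 (5 of 10). In MI-E against MI there was 1 gene against at most 1 (2 of 10), and 10 lists against at most 16 (4 of 10). In Sham-E against Sham there were 0 genes against at most 0 (10 of 10), and 10 lists against at most 13 (9 of 10). In MI-E against Sham-E there were 0 genes against at most 0 (10 of 10), and 8 lists against at most 16 (10 of 10). The median over the other splits was 8, 8, 12 and 12 lists in the order above, against 9, 10, 10 and 8 in the real splits. The number of lists past camera with the preset correlation therefore did not set the real groups apart.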
